A study of Mus musculus with 2 samples.

How the data were processed

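Droplet single-cell RNA sequencing (10x Genomics Chromium) was used on collagen gels that held mouse bone marrow-derived macrophages and NIH/3T3 cells, an immortalised mouse embryonic fibroblast line, seeded 1 to 1. The 2 libraries are titled as an unwounded and a wounded gel, with 1 library in each group. The treatment tag gives none for the unwounded and a 0.2 mm puncture for the wounded gel, while the treatment protocol describes the puncture for both, so groups rest on the titles and the tag. Gels were dissolved with collagenase, dead cells were depleted and the suspension was loaded on the droplet controller, per the labels' protocols.

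The unwounded library's deposited values are UMI counts per gene and barcode, which are whole numbers with no normalization. Cell Ranger 3.1.0 and the mm10 build are named in the submitters' processing notes, and the file names describe the barcodes as filtered, while the criteria of that filter are not given in the sources used here. For the wounded library, the barcode list and the gene list were used and its expression was not analysed here, so no gene was compared between wounded and unwounded gels. Both gene lists were identical and held 31053 genes. Barcodes of the unwounded library held between 500 and 262907 UMIs.

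Barcodes with at least 500 genes and at most 15% mitochondrial UMIs were kept (9529 of 10968). Scrublet, run through scanpy 1.11.5 with an expected rate of 8%, marked 71 of them (0.745%) as doublets, and 9458 remained. Counts were scaled to 10000 per cell and log-transformed. All 366 list genes found in the table were left out before 2000 highly variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1. The 20 macrophage and 20 fibroblast markers that name clusters were fixed before the data were examined. The thresholds of the naming rule were set later. A cluster stayed unnamed when its summed markers of both classes reached 10% of the highest cluster among those of at least 100 cells, or when its median UMIs were under the kept barcodes' median divided by 3 with no marker among its 10 leading genes. Cluster names were rebuilt here and are not the authors' annotation.

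Counts were summed per class and divided by the class total and expressed as CPM, the share of a class's UMIs scaled to 1000000. Genes with at least 100 UMIs over both classes were compared, and a fold of at least 4 named a gene as higher in a class. A count of 0 was set to a floor of 3 counts for a fold. With 1 library there was no replicate, so no test was run. Intervals at 95% are exact Poisson intervals for sums, the conditional binomial for ratios and exact Clopper-Pearson for shares, and they cover counting error only. The fixed rule for named genes took all measured genes of the CSF1 and PDGF circuit. From every other list it took the 2 members with the largest absolute log2 ratio among those at 50 CPM or more. Outside lists and markers it took the 5 genes per direction with the largest fold at 200 CPM or more. Between clusters of one class it took the 3 members with the largest fold from the 5 lists with the most members 2-fold apart. To describe each cluster it took its 5 leading genes at 100 CPM or more, list genes included.

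The 21 result lists were described by the median log2 ratio of measured members with a pseudocount of 1 CPM and by its percentile among 10000 random lists matched on mean expression. Members were counted as 2-fold higher on that same scale, and so were list genes 2-fold apart between clusters, while printed folds of single genes have no pseudocount. Cycling cells were those with at least 2 of 10 mitotic genes detected after every cell was thinned to 1000 UMIs. Ligand and receptor pairs were counted across classes when both genes reached 20 CPM. Newer gene symbols were matched through a synonym table, and Aldoa was left out because 2 features share its symbol. Positions come from GENCODE M21 on GRCm38, the assembly that mm10 names. Counts do not separate near-identical gene copies, so values of such genes are uncertain.

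On simulated sums for the class comparison (12783 genes), all 8-fold changed genes were called (100%), no 2-fold changed gene was called (0%), 0 unchanged genes were called and the ratio intervals held the true value for 95.2% of genes. The simulated counts were Poisson draws without free RNA, misnamed cells or variation between cells. They check the calculation and say nothing on the folds of the real data. Alternatives covered the cell filter, doublets, resolution, marker-only classes, per-cell means, TMM factors (edgeR 4.0.16), the minimum count, free RNA, the pseudocount, thinning and the pair threshold. Leaving out shallow barcodes found in both lists, naming low-depth clusters, thinning to 5000 UMIs, adding 1 CPM before the fold, counting list members by plain folds, and pairs or cluster lists under further settings were chosen after the data were seen.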

Results

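Macrophages and fibroblasts were profiled together in collagen gels after 48 h of coculture and a further 72 h of incubation, and the series concerns how the 2 cell types communicate during repair. The unwounded library held 10968 barcodes and 229189395 UMIs, with a median of 11899 UMIs and 3420.5 genes per barcode. The wounded library's list held 14701 barcodes. Each condition had 1 library, so values below describe this unwounded library and carry counting error only.

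Macrophage-like cells outnumbered fibroblast-like cells among those that could be named. There were 4114 macrophage-like and 2437 fibroblast-like cells, a macrophage-like share of 62.8% (95% interval 61.6% to 64.0%, exact Clopper-Pearson) after seeding at equal numbers. Recovery of each cell type through collagenase, dead-cell depletion and droplet loading was not measured here. The share is therefore one of recovered barcodes and does not show a change of cell numbers in the gel. Fibroblast-like cells as named held a median of 52069 UMIs, against 14475.5 in macrophage-like cells. A further 2619 shallow barcodes (27.7% of those kept, median 1355 UMIs) stayed unnamed, in clusters whose markers were nearer to fibroblasts. Of these barcodes 95.9% also stood in the wounded library's list. A macrophage-like cluster that was also shallow (353 cells, median 1138 UMIs) kept its name because the marker Lyz2 was among its leading genes. With the 2619 barcodes counted in their nearer class the fibroblast-like median was 2956.5 UMIs, so the order of the depths rests on the naming rule. The macrophage-like share was then 44.9%, and classing each cell by markers alone gave 48.4%. Another 288 barcodes held markers of both classes and were set aside.

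The CSF1 and PDGF circuit was largely divided between the cell types, with Pdgfa as an exception. Csf1, the growth factor on which macrophage survival depends, stood at 74.6 CPM in fibroblast-like cells (73.2 to 76.1) and 5.71 CPM in macrophage-like cells (5.14 to 6.32), a fold of 13.1 (11.8 to 14.5). Its receptor Csf1r stood at 1187 CPM in macrophage-like cells and 12.9 CPM in fibroblast-like cells, 92.2-fold apart (88.0 to 96.8). Il34, the other ligand of that receptor, reached only 1.29 CPM in fibroblast-like cells against 0.0308 CPM from 2 UMIs (fold 42.0, 11.5 to 349.8). In the opposite direction, Pdgfb was 90.5-fold (58.3 to 149) and Pdgfc 5.12-fold (4.77 to 5.50) higher in macrophage-like cells, at 13.2 and 40.0 CPM. The PDGF receptors Pdgfra and Pdgfrb were 67.7-fold (59.3 to 77.7) and 54.3-fold (44.4 to 67.1) higher in fibroblast-like cells, at 227 and 79.3 CPM. Pdgfa was higher in fibroblast-like cells by 2.20-fold (2.05 to 2.37). Of the 8 members, 3 were at least 2-fold higher in macrophage-like and 5 in fibroblast-like cells, with a median log2 ratio of -1.12 (percentile 0.99 of matched random lists). Members lay on both sides, and this median falls between the scarce Il34 (-1.15) and Pdgfa (-1.09). Neither it nor its percentile describes a lean of the whole list. Here and below, list members were counted as 2-fold higher after 1 CPM was added to both classes, while folds of single genes are plain. All folds compare shares of a class's UMIs and not UMIs per cell. Fibroblast-like cells as named held more UMIs (median 52069 against 14475.5). Per cell, folds toward macrophage-like cells would be smaller or reversed and those toward fibroblast-like cells larger. Preset markers of the other class stood at 0.790% to 2.65% of their own level in fibroblast-like cells and 1.14% to 2.58% in macrophage-like cells, so a lower value up to the top of that range is read as free RNA. Csf1, Pdgfa and Pdgfc in the lower class lay above it.

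**Figure D1:**
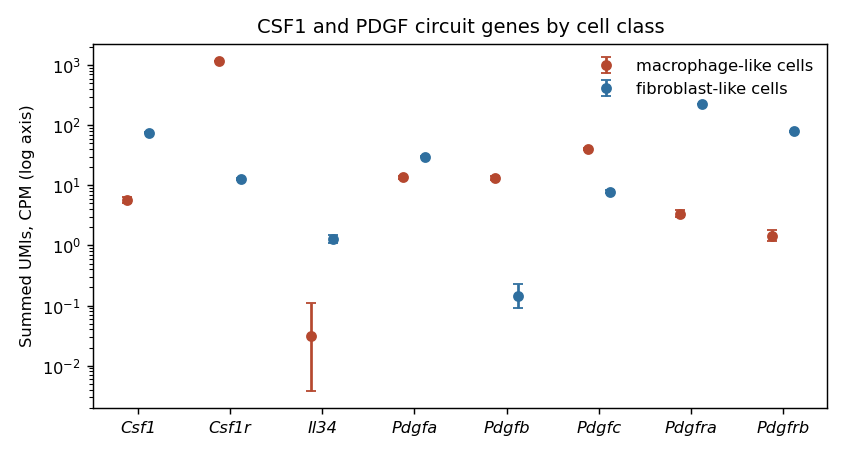
Summed UMIs as CPM on a log axis for the 8 genes of the CSF1 and PDGF circuit in macrophage-like (red) and fibroblast-like (blue) cells, with exact Poisson 95% intervals. Csf1 stood at 74.6 CPM in fibroblast-like cells and Csf1r at 1187 CPM in macrophage-like cells, while Pdgfra stood at 227 CPM in fibroblast-like cells.

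On GRCm38 (GENCODE M21) Csf1 lies on chromosome 3 from 107741048 to 107760469 and Csf1r on chromosome 18 from 61100598 to 61132149. Pdgfrb lies beside Csf1r on chromosome 18 from 61045150 to 61085061. Pdgfb lies on chromosome 15 from 79995874 to 80014977, Pdgfc on chromosome 3 from 81036416 to 81214040 and Pdgfra on chromosome 5 from 75152292 to 75198215. UMIs were counted per gene, so no exon or transcript is resolved.

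Across the transcriptome, 12809 genes had at least 100 UMIs. Of these, 1820 were at least 4-fold higher in macrophage-like cells and 2191 in fibroblast-like cells. Outside the lists and markers, the widest folds toward macrophage-like cells belonged to Xist (162-fold, 151 to 174), the RNA that silences an X chromosome in female cells, and to Cd28 (159.6-fold), Pou2f2 (145-fold), Cnrip1 (135-fold) and Cd84 (134-fold). Toward fibroblast-like cells they belonged to Gm10260 (128-fold, 119 to 139), Meg3 (91.3-fold), the transcription factors Ebf1 (90.3-fold) and Nfib (79.8-fold), and the secreted growth factor Ptn (82.0-fold), which reached 7194 CPM. Gm10260 is a predicted gene and its value is uncertain, and the lower class of all 10 genes stood no higher than the free RNA range, so these folds and their order depend on free RNA and the intervals cover counting error only. The order of the counts depended on low-count genes, and for macrophage-like and fibroblast-like cells in turn they were 1268 and 1150 with at least 1000 UMIs, and 1485 and 1319 with 1 CPM added before the fold.

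Macrophage-like cells expressed alternative activation, lipid-handling and complement genes. List medians and percentiles compare 2 classes that were named by cell type markers. They describe differences between cell types, not activation state or pathway activity. Of 14 measured alternative activation genes, 12 were at least 2-fold higher in macrophage-like and 2 in fibroblast-like cells (median log2 ratio 4.14, percentile 100), including the mannose receptor Mrc1 at 1633 CPM (99.6-fold, 95.5 to 104) and the lectin Clec10a (89.3-fold). Arg1, Chil3, Retnla and Timd4 had 0 UMIs in macrophage-like cells, and Lyve1 had 3. Of 20 lipid and lysosome genes 15 were higher and 1 lower (median 2.72, percentile 100), with the lipid carrier Apoe at 8427 CPM and Gpnmb at 2114 CPM. Complement genes were higher in 7 of 11 (median 5.22, percentile 100), with C1qa at 1846 CPM and the receptor C3ar1 at 506 CPM, while 3 were higher in fibroblast-like cells (4 by plain folds). Pro-inflammatory genes were higher in 8 of 12 and lower in 2 (median 2.40, percentile 100), yet only Nfkbia reached 50 CPM, at 85.0 against 67.4 CPM, and Nos2 had 0 UMIs. Class II antigen presentation genes were higher in 6 of 7 and lower in 0 (1 by plain folds, median 2.53, percentile 99.93) with none at 50 CPM.

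Chemotactic, interferon and adhesion genes also leaned to macrophage-like cells. Of 16 chemokines 8 were higher there, with Ccl4 (120.4-fold) and Ccl6 (106-fold) widest, and 5 were higher in fibroblast-like cells (median 1.84, percentile 99.96). Of 5 chemokine receptors 4 were higher and 1 lower (median 5.40, percentile 100), including Ccr1 (174-fold) and the complement receptor C5ar1 (106-fold). Interferon response genes were higher in 14 of 16 and lower in 1 (median 1.73, percentile 99.99), with Ifi27l2a at 966 against 94.5 CPM and Oasl2 16.8-fold higher. Integrins and related adhesion genes were higher in 8 of 14 and lower in 2 (3 by plain folds, median 1.84, percentile 99.97), including Sirpa (58.7-fold) and Itga4 (121-fold). Immediate early genes were divided, with 6 of 16 higher in macrophage-like and 2 in fibroblast-like cells (median 0.28, percentile 57.1), and Atf3 and Fos were 21.1-fold and 4.78-fold higher in macrophage-like cells.

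Fibroblast-like cells carried the matrix and contractile genes. Of 24 extracellular matrix genes 21 were at least 2-fold higher there (23 by plain folds) and 0 in macrophage-like cells (median -4.59, percentile 0), with fibronectin (Fn1) at 489 CPM (47.2-fold) and Fbln2 at 273 CPM (49.2-fold). Matrix remodelling genes were higher in 15 of 23 (16 by plain folds, median -2.47, percentile 0), including the protease Adamts5 (81.9-fold) and the inhibitor Timp3 (57.4-fold), and 3 were higher in macrophage-like cells. Contractile genes were higher in 15 of 18 and lower in 1 (median -3.02, percentile 0), with Acta2, smooth muscle actin, 60.2-fold and Tpm2 55.1-fold higher. YAP response genes were higher in 10 of 12 (median -4.01, percentile 0), including Cavin2 (68.0-fold) and Tead1 (57.5-fold), and TGF-beta response genes in 8 of 14 (median -1.79, percentile 0.01), including Ltbp1 (52.4-fold) and Pmepa1 (30.6-fold), while 4 were higher in macrophage-like cells.

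Growth factors were expressed by both classes. Of 16 growth factors 6 were higher in macrophage-like and 8 in fibroblast-like cells (median -0.81, percentile 6.10), with Igf1 25.3-fold higher in macrophage-like cells at 717 CPM and Fgf7 70.3-fold higher in fibroblast-like cells at 71.4 CPM. Growth factor receptors were higher in fibroblast-like cells in 9 of 18 (10 by plain folds, median -1.08, percentile 0.0600), including Fgfr1 (42.3-fold) and Tgfbr3 (35.1-fold), and 5 were higher in macrophage-like cells. Hypoxia and glycolysis genes were higher in fibroblast-like cells in 6 of 17 and lower in 1 (median -0.59, percentile 5.36), with Eno1 2.89-fold and Tpi1 2.11-fold higher. S phase genes were higher there in 10 of 24 (11 by plain folds, median -0.73, percentile 0.5), while Pcna, named after its values were seen, was 6.27-fold higher in macrophage-like cells. G2 and M phase genes were higher in fibroblast-like cells in 17 of 24 (19 by plain folds, median -1.24, percentile 0), with Cenpf 6.16-fold higher and Ube2c at 89.5 against 28.9 CPM.

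**Figure D2:**
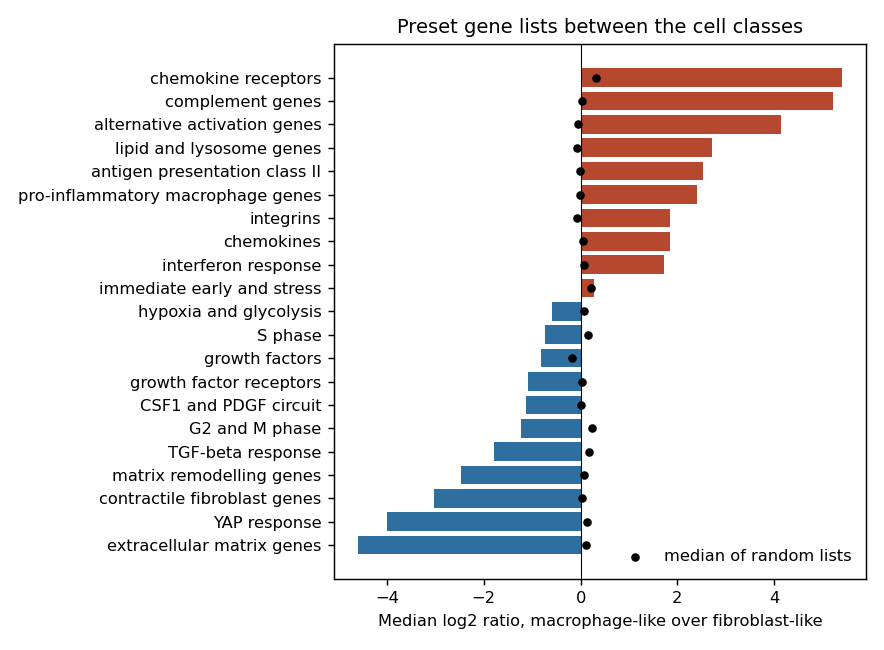
Median log2 ratio (macrophage-like over fibroblast-like, pseudocount 1 CPM) of the measured members of each of 21 preset gene lists, as bars, with the median of matched random lists as black points. Chemokine receptors (5.40) and complement genes (5.22) lay at the macrophage-like end and extracellular matrix genes (-4.59) at the fibroblast-like end.

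More fibroblast-like than macrophage-like cells were cycling. After thinning to 1000 UMIs, 181 of 2437 fibroblast-like cells (7.43%, 6.42% to 8.54%) and 105 of 3971 macrophage-like cells (2.64%, 2.17% to 3.19%) had at least 2 of the 10 mitotic genes, and 143 shallower macrophage-like cells were left out. Without thinning the shares were 49.2% and 15.2%. The summed 10 genes stood at 611 CPM and 217 CPM in the same order. Shares depended on depth, and at 5000 UMIs they were 14.6% and 4.94%.

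Macrophage-like cells formed 6 clusters. Cluster 3 (1312 cells) was led by Clec10a, Tfrc, Hist1h1c, Dusp6 and Lpin1, cluster 4 (1227 cells) by F13a1, Tmem176a, Tmem176b, Ccl8 and Ly6e, and cluster 7 (548 cells) by Fabp4, Atp6v0d2, Gadd45a, Bcl2a1b and Slc15a3. Cluster 8 (573 cells) was led by Mfge8, Lsp1, S100a4, S100a6 and Lpl, and cluster 11 (101 cells) by the cell cycle genes Nusap1, Prc1, Top2a, Hist1h1b and Pclaf. Among these, Clec10a, Ccl8, Fabp4, Lpl, Nusap1 and Top2a are list genes, which took no part in the clustering. Cluster 10 (353 cells, median 1138 UMIs) was led by Ccdc152, AY036118, Fabp4, S100a6 and Ptn. Ptn stood there at 184 CPM against 7194 CPM in fibroblast-like cells, within the free RNA range. Xist stood at 442 CPM in cluster 10 and at 838 to 1284 CPM in the other macrophage-like clusters. Of its barcodes 44.5% were in the wounded library's list, more than in clusters 3, 4 and 7 and fewer than in clusters 8 and 11. Whether all of them were cells of this gel stays open.

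Lipid and chemokine genes, which took no part in the clustering, differed between macrophage-like clusters. The clusters were still cut from other genes of the same cells, which can vary together with list genes. For each gene the highest cluster was set against the lowest. In both classes the counts of genes apart therefore describe the clusters and are no independent support for them. Of 20 lipid and lysosome genes at 50 CPM or more 12 were at least 2-fold apart with 1 CPM added. Fabp4, a fatty acid carrier, ran from 6.73 CPM in cluster 4 to 253 CPM in cluster 7 (37.6-fold, 31.9 to 44.6), and Lpl and Lgals3 were 7.38-fold and 5.18-fold higher in cluster 8 than in cluster 3. Among chemokines 5 of 9 were apart, with Ccl8 at 350.2 CPM in cluster 4 and 18.2 CPM in cluster 11 (19.2-fold, 14.7 to 25.7) and Ccl4 and Ccl6 highest in cluster 7. Immediate early genes were apart in 6 of 10, including Atf3 (4.54-fold, cluster 8 over 4), Dusp1 (3.69-fold, 1.96 to 7.83, cluster 11 over 10) and Egr1 (3.40-fold, 2.20 to 5.58, cluster 4 over 10), which rest on 10 and 20 UMIs in the shallow cluster 10. All 24 G2 and M phase genes and 16 S phase genes were apart, and cluster 11 was highest for Birc5, Ccnb2, Ube2c, Rrm2, Uhrf1 and Clspn (Birc5 469 against 1.63 CPM in cluster 4). Cluster 11 was led by cell cycle genes that were not left out of the clustering, such as Prc1, Hist1h1b and Pclaf. Differences in these 2 lists therefore follow from how that cluster was formed. In all, 90 list genes were 2-fold apart, with those 24 and 16 cell cycle genes included. The number was 49 when shallow barcodes found in both lists were left out.

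Fibroblast-like cells formed 4 clusters, of which 3 held at least 100 cells. Cluster 2 (762 cells) was led by Nbl1, Sparcl1, Mgp, Mfap4 and Gsta4, cluster 5 (1101 cells) by Vegfd, Ptx3, Sfrp2, Emb and Rab9, and cluster 6 (478 cells) by Hist1h2ap, Prc1, Hmmr, Cdc20 and Hist1h1b. Hmmr is a list gene and took no part in the clustering. Cluster 12 (96 cells) was led by Col12a1, Ogn, Aspn, Nupr1 and Pdgfrl. Of 15 extracellular matrix genes at 50 CPM or more 5 were at least 2-fold apart between clusters 2, 5 and 6. Postn, a matricellular protein, stood at 805 CPM in cluster 2 and 78.1 CPM in cluster 6 (10.3-fold, 9.90 to 10.7), and Fbln2 and Thbs2 were 2.82-fold and 2.77-fold higher in cluster 2 than in cluster 6. Of 12 remodelling genes 9 were apart, with Mmp2 (5.56-fold) and Mmp11 (5.29-fold) higher in cluster 2 and Mmp9 higher in cluster 6 (68.3 against 20.6 CPM in cluster 5). Spp1 was highest in cluster 2 at 985 CPM, Lpl in cluster 5 at 183 CPM and Fabp5 in cluster 6 at 540.5 CPM. Ube2c, Birc5, Hmmr, Uhrf1, Mcm5 and Hells were highest in cluster 6. That cluster was led by cell cycle genes that were not left out of the clustering, such as Prc1 and Cdc20. Higher cell cycle list genes there follow from how the cluster was formed. In all, 75 list genes were 2-fold apart at resolution 1, among them 20 G2 and M phase and 9 S phase genes. At resolution 2 the number was 120.

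**Figure D3:**
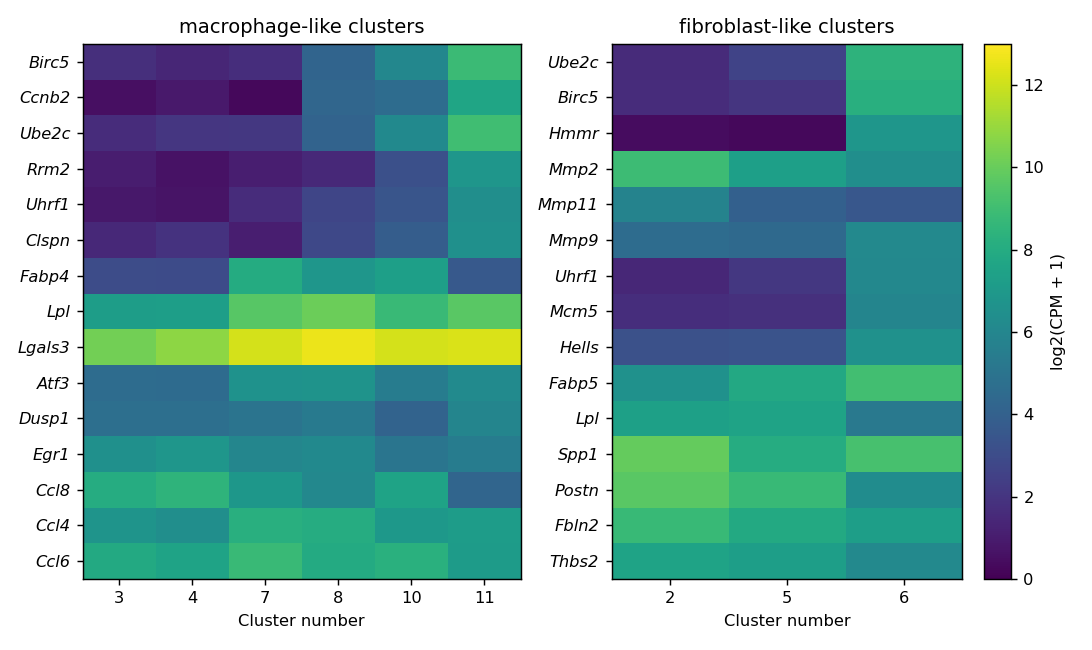
Expression, as log2 of CPM plus 1, of the named list genes in macrophage-like clusters (left) and fibroblast-like clusters (right) of at least 100 cells, with cluster numbers on the x axis. Fabp4 was highest in cluster 7 (253 CPM) and Postn in cluster 2 (805 CPM).

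Ligand and receptor transcripts were paired in both directions. Of 40 preset pairs, 9 ran from macrophage-like to fibroblast-like cells and 12 the other way, with 6 counted both ways, and these are co-occurring transcripts only. By the same 20 CPM rule 11 pairs were counted within macrophage-like cells and 9 within fibroblast-like cells. From macrophage-like cells, Apoe (8427 CPM) paired with Lrp1 (117 CPM), Gas6 (1321 CPM) with Axl (77.8 CPM), Igf1 (717 CPM) with Igf1r (72.4 CPM), and Spp1 (836 CPM) with Itgav (30.8 CPM) and Cd44 (26.6 CPM). From fibroblast-like cells, Cd47 (112 CPM) paired with Sirpa (1212 CPM), Csf1 (74.6 CPM) with Csf1r (1187 CPM), Spp1 (558 CPM) with Cd44 (136 CPM), Apoe (106 CPM) with Lrp1 (176 CPM) and Cxcl12 (267 CPM) with Cxcr4 (54.2 CPM). For Apoe with Lrp1, Cd47 with Sirpa and Spp1 with Cd44, the product of ligand and receptor CPM was larger within macrophage-like cells than across. The other pairs named so far had their largest product across the classes. Apoe in fibroblast-like cells lay within the free RNA range, and so did Sirpa there (20.6 CPM), on which its pair with Cd47 from macrophage-like cells rested. With free RNA subtracted, a setting chosen after the data were seen, 8 and 11 pairs across the classes were left. At 50 CPM the pairs across fell to 3 and 6.

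Markers of other cell types were mostly near 0. The neutrophil genes S100a8 and S100a9 reached 39.4 and 51.7 CPM in cluster 4, while Ly6g, Ltf, Mpo and Elane had 0 UMIs in macrophage-like cells. Mmp8 stood there at 2.26 CPM and Ngp had 6 UMIs. The B cell list's Ighm stood at 157 CPM and Cd79b at 2.37 CPM in macrophage-like cells, whereas Ms4a1 and Pax5 had 0 UMIs there. The osteoclast list's Atp6v0d2 reached 323 CPM in cluster 7 with Calcr, Ocstamp, Dcstamp and Oscar at 0 UMIs in macrophage-like cells. In fibroblast-like cells the dendritic cell list's Fscn1 stood at 100.5 CPM, the megakaryocyte list's Itga2b at 23.4 CPM, the mast cell list's Gata2 at 11.0 CPM and the endothelial list's Egfl7 at 13.5 CPM. Of the T or NK cell list Cd3e, Ncr1 and Gzma had 0 UMIs, and so did Hbb-bs and Hbb-bt of the erythroid list.

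The barcode lists of the libraries overlapped. Of 10968 unwounded and 14701 wounded barcodes, 7010 stood in both lists (63.9% of the unwounded and 47.7% of the wounded ones). Among fibroblast-like cells 85.7% and among macrophage-like cells 27.2% were in both lists. The overlap was 0.147% among barcodes of 5000 to 10000 UMIs (0.00372% to 0.815%) and 89.1% at 40000 UMIs or more (87.8% to 90.3%).

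**Figure D4:**
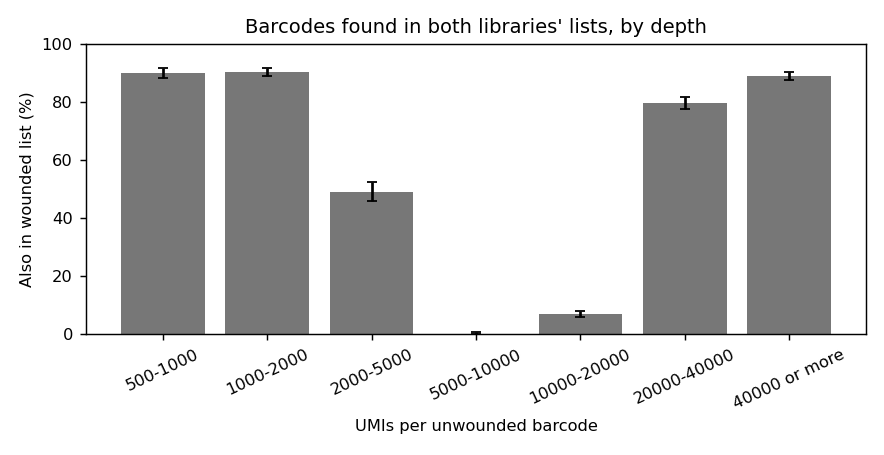
Percent of unwounded barcodes that also stand in the wounded library's list (y axis) by UMIs per barcode (x axis), with exact binomial 95% intervals. The share was 90.1% at 500 to 1000 UMIs, 0.147% at 5000 to 10000 and 89.1% at 40000 or more.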

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

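All tests in this part were chosen after the values were seen. Data outside the expression comparison, the wounded library's barcode list, shared 7010 barcodes with the unwounded list, of which 3592 held under 5000 UMIs. Chance draws of the same barcode would give a like share at every depth, but the share was 88.9 percentage points higher at 40000 UMIs or more than at 5000 to 10000. Cells listed for both libraries would be shared at middle depth too, where 0.147% were. A candidate explanation is that molecules of deep cells were carried into the other library under their barcode, but the gap of 88.7 percentage points or more within barcodes nearer to each class shows only that cell type did not make that gap. Among shallow barcodes the share did differ by nearer class. For macrophages and fibroblasts in turn it was 83.8% and 96.0% at 500 to 1000 UMIs, 40.4% and 98.0% at 1000 to 2000, and 2.31% and 90.6% at 2000 to 5000. Whether carrying took place, and whether it gave the shallow shared barcodes (90.1% at 500 to 1000 UMIs), stays open without the wounded counts, and no biological explanation was tested.

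Cluster 9 (288 barcodes) held markers of both classes. Free RNA is argued against, since its median macrophage marker stood at 25.7% of the macrophage-like level against at most 2.65% in fibroblast-like cells. A macrophage and a fibroblast in one droplet is a candidate. Xist, which was no marker, stood at 23.6%, inside the markers' range of 19.2% to 29.5%. Any source of macrophage RNA would bring Xist along with the markers, so this cannot single out shared droplets. The median of 51569.5 UMIs in cluster 9 was no higher than the 52069 of fibroblast-like cells. Whether any such pairs of cells were drawn at random from the named clusters stays undecided, since 3 of 1273 genes (Cbx6, Med13l and H19) exceeded their highest named cluster by over 1.5 times and at least 5 had been set as the bound against it. No biological explanation was tested.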

How the results depend on the processing

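Every named gene and list median kept its sign under each alternative run for it. The naming of shallow barcodes moved the macrophage-like share most: it was 61.3% with no cell filter, 67.0% with the stricter filter, 60.6% with doublets kept, 61.1% at resolution 2, 48.4% from markers alone and 44.9% with low-depth clusters named, so whether macrophage-like cells were the majority depends on those barcodes. Of the 2619 shallow unnamed barcodes 95.9% stood in both lists. Without shallow barcodes found in both lists, 3962 macrophage-like and 2450 fibroblast-like cells were named. The cycling share of fibroblast-like cells was 9.77% with the stricter filter, 9.70% from markers alone and 10.7% with low-depth clusters named. For fibroblast-like and macrophage-like cells in turn it was 49.2% and 15.2% with no thinning, 4.47% and 1.84% with at least 3 genes, and 14.6% and 4.94% at 5000 UMIs, and fibroblast-like cells were higher in each. Genes 4-fold higher in fibroblast-like cells numbered 1150 with a minimum of 1000 UMIs, where fewer genes are tested, and 1319 with 1 CPM added before the fold, which lowers the folds of scarce genes. List genes 2-fold apart numbered 49 between macrophage-like clusters without shallow barcodes found in both lists, and 120 between fibroblast-like clusters at resolution 2, and the cause was not tested. At 50 CPM, 3 and 6 pairs were left. Settings with named low-depth clusters, without shallow barcodes, at 5000 UMIs or with 1 CPM added were chosen after the data were seen. Of 252 list medians under alternatives 226 stayed within 0.2 of the main value, and a pseudocount of 10 CPM moved them by a median of 1.13. Free RNA subtraction moved single genes by a median of 1.24 on the log2 scale, so folds whose lower class lies no higher than the free RNA range are limited by it.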

Other observations

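The genes and the test in this part were chosen after their values were seen. Fibroblast-like cluster 6, where 37.2% of cells were called cycling, held 3 chemokines at higher levels than clusters 2 and 5. Ccl5 stood at 93.9 CPM in cluster 6 (90.7 to 97.2) and at 1.82 and 1.55 CPM in clusters 2 and 5. Ccl2 stood at 156 CPM in cluster 6, at 28.2 to 31.8 CPM (its 95% interval) in cluster 2 and at 11.7 CPM in cluster 5, and Ccl7 at 108 CPM in cluster 6 against 32.6 and 34.4 CPM in clusters 2 and 5. Cxcl12 went the other way, from 382 CPM in cluster 2 to 96.9 CPM in cluster 6, while Csf1 ranged only from 70.8 to 75.7 CPM across the 3 clusters. Csf1 does not stand for its list, since 2 of 3 CSF1 and PDGF circuit genes at 50 CPM or more were at least 2-fold apart there.

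Sex-linked transcripts separated the cell sources. Xist stood at 905 CPM in macrophage-like and 5.58 CPM in fibroblast-like cells, while the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 1.17 and 76.4 CPM. In clusters 0 and 1, unnamed for low depth, they summed to 76.8 and 62.0 CPM, the lower being 81.2% of the fibroblast-like level, and Xist stood there at 42.8 and 15.8 CPM. The shallow barcodes of those 2 clusters may therefore hold fibroblast RNA, though not alone, since Xist exceeded the fibroblast-like level. Of the barcodes in clusters 0 and 1, 98.2% and 93.4% also stood in the wounded library's list. Whether they were cells of this gel stays open. These statements leave out the unnamed cluster 13 (28 barcodes), where the Y-linked sum was 19.8 CPM and Xist 317 CPM.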
